A study of Mus musculus with 6 samples.

How the data were processed

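RNA was sequenced from whole mouse aorta in 6 libraries, 3 from mice with a floxed Ogt gene that served as controls and 3 from mice with Ogt deleted in smooth muscle cells. Groups and replicate numbers came from the genotype labels and sample titles. The labels do not say how many mice went into a library, so p-values here measure the spread between these libraries, part of which may be technical. Per the submitters' processing notes, the tools named were CASAVA 1.8, HISAT2, SAMtools 1.3.1 and edgeR. The program that counted reads per gene, its annotation and its strand setting are not given in the sources used here. Reads of overlapping or antisense genes, and of genes with near-identical copies, are therefore uncertain.

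The deposited table gave, per the file headers, a read count and an FPKM value (fragments scaled by gene length and library total) for each of 55487 genes in each library, with gene symbols and positions. The counts the authors deposited were whole numbers with a different total in each library. The FPKM values the authors deposited equalled the count divided by 1 length per gene and by the library total. Over the 7705 genes with at least 50 counts in every library, the gene length implied by counts and FPKM differed between libraries by at most a relative 1.1e-05. FPKM were used only for that check. The submitters' processing notes name the build GRCm39, yet of the 55227 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 54907 (99.4%) had identical positions and 320 had another. Positions are therefore given as GRCm38 coordinates, as the table lists them. A further 114 symbols belonged to more than 1 identifier, and the identifier with the highest total count was used for these. No numeric column was left unmapped to a sample. Gapdh, which has many processed pseudogenes, had 46 to 289 counts per library against 927 to 6744 for the main Aldoa entry. Counts of genes with many near-identical copies are therefore taken as uncertain.

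Counts were analysed as deposited in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 16139 genes. Libraries were scaled with trimmed mean of M values (TMM), and groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust estimation on), a quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are knockout minus control. Their standard error is the size of the log2 fold change divided by the square root of the F statistic. Expression is given as CPM, the count scaled to the TMM-adjusted library size, as mean ± SD with n = 3 per group. No covariate entered the model. Before the data were examined, 39 gene lists were fixed for smooth muscle states, metabolism, stress, inflammation, matrix and the other cell types an aorta can hold, with 788 entries, of which 787 were found in the table and 25 genes stood in more than 1 list. The 36 lists with at least 5 tested members were compared with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with the correlation estimated per list. The fry test, which asks whether a list's genes move on balance one way, was run as a further alternative. Member calls were also counted after adjustment over the list alone.

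The genes named were chosen by a rule fixed at the same time as the lists. It took Ogt; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM, knockout libraries all on the same side of all control libraries, and a symbol that is not a predicted-gene name; and up to 4 members of each list with the smallest unadjusted p. It also took Oga, Acta2, Myh11, Tagln, Cnn1, Myocd, Runx2, Spp1, Klf4, Mki67, Hspa5, Ddit3, Xist and Ddx3y whatever their values. Any gene outside the rule is said to have been chosen after its values were seen. Not every gene that the rule takes is reported here.

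The steps were tested on simulated counts for the 16139 genes, drawn with the real means and library sizes and with 200 genes changed. The test called 29% of genes changed 2-fold and 74% of genes changed 4-fold, and 11 of its 117 calls were genes that had not been changed. A list of 25 genes raised 1.5-fold was called by camera with an adjusted p of 1.24e-12, and 0 other lists were. The simulated genes were drawn independently of one another. The list step was therefore not tested for lists whose genes are correlated, as those of the real data can be. With no change simulated, 1 gene was called higher, and genes called lower were not counted. Total counts ran from 3038782 in control replicate 2 to 18218385 in knockout replicate 3, so values of rare transcripts in control replicate 2 rest on few reads. Pairs of libraries within a group differed far beyond counting error, with a mean chi-square per gene of 17.4 to 174.6, so no library was taken for a copy of another, which does not show that they came from separate mice.

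Alternatives were DESeq2 size factors or library size in place of TMM, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 or limma-voom with sample weights in place of edgeR, robust estimation off, a minimum absolute log2 fold change of 1, the replicate number as a block, removal of a trend with gene length or GC content, and leaving out each library in turn. Figures and summaries were made with Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Read-level data, splicing and protein O-GlcNAc levels were not analysed here.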

Results

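Whole-aorta RNA from mice with Ogt deleted in smooth muscle cells was compared with that of floxed control mice, to find genes regulated by Ogt in the vessel wall. Ogt encodes O-GlcNAc transferase, the enzyme that attaches N-acetylglucosamine to serine and threonine residues of nuclear and cytoplasmic proteins. Each group had 3 libraries. Total counts were 13738958, 3038782 and 12929900 in control replicates 1 to 3 and 11845644, 17223643 and 18218385 in knockout replicates 1 to 3. Control replicate 2 stood apart from the other libraries in composition as well as depth. Mitochondrial ribosomal RNA took 10.2% of its counts against 0.491% to 0.823% elsewhere, Malat1 took 1.63% against 0.219% to 0.305%, and protein-coding genes took 77.2% against 93.2% to 94.2%. The first principal component, with 54.4% of the variance, separated that library from the other 5. The second component, with 19.1%, placed control replicates 1 and 3 at -41.2 and -34.9 and the knockout libraries at 10.4 to 29.8, with control replicate 2 at 13.6, inside the knockout range.

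Ogt (ENSMUSG00000034160; GRCm38 chromosome X, 101640060 to 101684351) was lower in each knockout library than in every control library. Control replicates 1 to 3 had 177.4, 183.2 and 150 CPM and knockout replicates 1 to 3 had 93.3, 73.5 and 70.9 CPM. Mean expression went from 170.2 ± 17.7 to 79.2 ± 12.3 CPM (SD, n = 3), which is 46.6% of control, in a tissue where cells outside the deleted lineage also contribute RNA. The log2 fold change was -1.102 ± 0.152 (SE), with an adjusted p of 0.0214 in edgeR's quasi-likelihood test. Oga, which encodes the enzyme that removes O-GlcNAc (ENSMUSG00000025220; chromosome 19, 45750259 to 45783837), fell as well, from 114.1 ± 6.65 to 64.7 ± 3.10 CPM (log2 fold change -0.82 ± 0.11, edgeR adjusted p = 0.0198). Among the 16 tested genes of the hexosamine pathway and O-GlcNAc cycling, Ogt and Oga were the 2 that fell and the other 14 were not called. Adjusted over the list alone, 3 were lower and 1 was higher, the additional members being Gnpda2 (log2 fold change -0.65) and Nagk (0.66), which handle glucosamine phosphate and free N-acetylglucosamine. The list as a whole was not called (median log2 fold change -0.08, camera adjusted p = 0.33). The Ogt call was lost without control replicate 1 (edgeR adjusted p = 0.105), knockout replicate 1 (0.0729), knockout replicate 2 (0.126) or knockout replicate 3 (0.0732), while the log2 fold change stayed between -1.23 and -1.02.

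**Figure D1:**
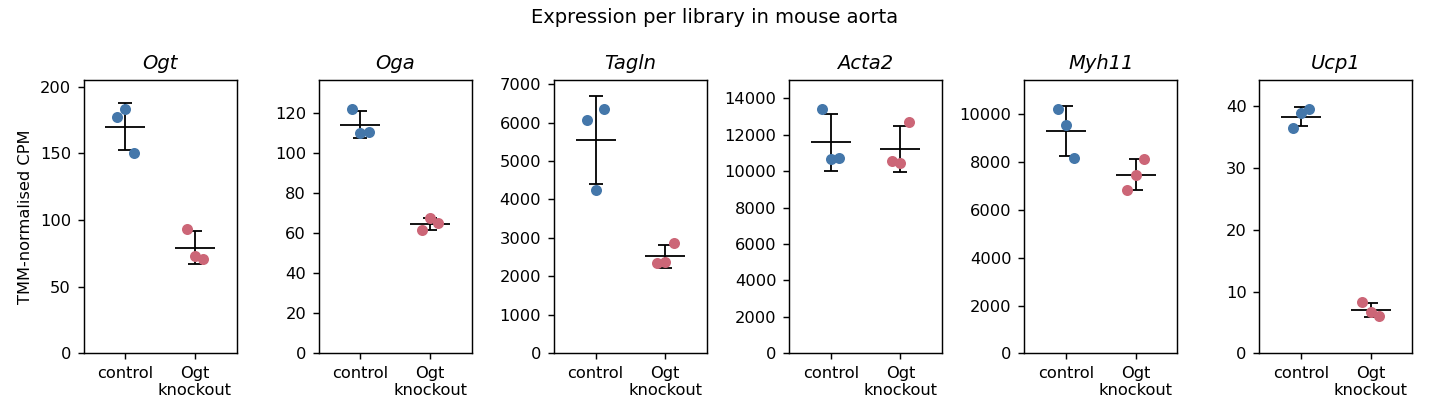
TMM-normalised CPM of Ogt, Oga, Tagln, Acta2, Myh11 and Ucp1 in each library (points), with the group mean (bar) and SD (whiskers) of 3 control and 3 knockout libraries. Ogt lay at 150 to 183.2 CPM in controls and at 70.9 to 93.3 CPM in knockouts, while the Acta2 values of both groups overlapped.

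The knockout aorta differed from control in 557 of 16139 tested genes, with 306 higher and 251 lower. Ckm, the muscle creatine kinase (chromosome 7, 19404776 to 19422841), rose from 3.19 ± 0.518 to 51.0 ± 10.7 CPM. Camkk1, a kinase that activates calcium/calmodulin-dependent kinases and AMPK (chromosome 11, 73019008 to 73042073), rose from 34.3 ± 11.7 to 328.6 ± 64.5 CPM. Casq1, the calcium-binding protein of the skeletal muscle sarcoplasmic reticulum, fell from 69.0 ± 9.31 to 16.8 ± 6.25 CPM.

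The remaining large rises were Ctxn1 (9.03 ± 1.48 to 64.6 ± 5.58 CPM), the synaptic vesicle gene Syngr3 (2.59 ± 1.38 to 19.2 ± 4.58 CPM), the secreted protein gene Scube1 (0.550 ± 0.233 to 5.43 ± 0.408 CPM), and 5 genes close to the detection limit in controls. Of these 5, the tight junction gene Tjp3 had 0 counts in the control libraries and 90 in the knockout libraries. Its pooled knockout level was 19.7-fold above 3 counts over the control group (0.0968 CPM), taken as the limit that a count of 0 allows. The spread of the knockout libraries does not enter that value, so it is not a strict lower bound. Slc7a4, Ptchd4, Rhpn1 and Brsk2 had control means of 0.140, 0.236, 0.212 and 0.317 CPM and knockout means of 2.04, 3.28, 2.95 and 1.72 CPM. The other large falls were the zinc finger genes Zfp62 (32.5 ± 7.20 to 4.36 ± 0.379 CPM), Zfp239 (log2 fold change -2.48) and Zfp759 (-2.04), the brown fat uncoupling protein gene Ucp1 (-2.45), the apoptosis inhibitor gene Faim2 (-2.88), the small GTPase gene Rab17 (-2.32), the sodium channel gene Scn2a (-2.19), the actin regulator gene Abi2 (-2.10) and the adhesion molecule gene Igsf9 (-1.98). Zinc finger genes of this family have similar copies, so reads could be divided between them. Adjusted p-values of these 20 genes in edgeR's quasi-likelihood test ran from 0.00152 for Ckm and Ctxn1 to 0.0483 for Brsk2. In all 557 genes the knockout and control values did not overlap, as was the case for 31.8% of all tested genes against 10% by chance. At an unadjusted p under 0.05 there were 3665 genes, against 807 by chance. Over all 16139 tested genes DESeq2 called 1501 and limma 1918, and the counts of list members below are to be read beside these numbers.

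The number of calls rested on single libraries. All 557 genes kept their direction in each of the 6 fits that left out a library and tested them. That outcome was all but fixed in advance, since their knockout and control values do not overlap, and it does not bear on how firm the calls are. There were 7 calls without control replicate 1, 911 without control replicate 2, 280 without control replicate 3, and 12, 13 and 33 without knockout replicates 1, 2 and 3, and 4 of the 50 named genes that were called (Ckm, Ctxn1, Ucp1 and Zfp62) passed the threshold in all 6 of those fits.

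Of the 36 gene lists tested, 4 were lower and 2 were higher in the knockout, and each of these calls was lost when the correlation between genes was estimated. The brown adipocyte list, of thermogenic genes, was called lower by camera with the preset correlation. Of its 13 tested members, 4 were lower and 9 were not called, and 9 were lower when adjusted over the list alone. Ucp1 went from 38.4 ± 1.57 to 7.03 ± 1.18 CPM, and the respiratory chain subunit genes Cox8b (log2 fold change -1.41 ± 0.26) and Cox7a1 (-1.78 ± 0.36) and the coenzyme A synthesis gene Pank1 (-0.94 ± 0.16) fell with it. Log2 fold changes were negative for 12 members and positive for 1, but the members fell unevenly. Chosen after their values were seen, Cidea (-0.34, edgeR adjusted p = 0.369), Ppargc1a (-0.60, 0.44) and Prdm16 (-0.78, 0.123) had overlapping groups and were not called. The list's median log2 fold change was -0.94 (camera adjusted p = 2.44e-05, and adjusted p = 0.786 with an estimated correlation). White adipocyte genes had a median of -0.04, with 0 of 18 called by edgeR, 4 at an unadjusted p under 0.05, 0 called by DESeq2 and 2 by limma.

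The list of immediate early genes, transcription factors and regulators induced within minutes of a stimulus, was also called lower with the preset correlation. Of its 22 tested members, 6 were lower and 16 were not called, and adjusted over the list alone 10 were lower and 1 (Maff) was higher. Egr1 (chromosome 18, 34859823 to 34864984) went from 185.9 ± 15.5 to 50.01 ± 10.1 CPM and Fosb from 47.9 ± 8.57 to 15.7 ± 0.923 CPM, and Nr4a2 (log2 fold change -1.15 ± 0.19), Btg2 (-0.998 ± 0.160), Junb (-1.22 ± 0.23) and Nr4a1 (-1.35 ± 0.28) were the other members that fell. Junb, Nr4a1 and Maff lie outside the naming rule and were chosen after their values were seen. The median of the list was -0.52 (camera adjusted p = 2.47e-05, and adjusted p = 0.786 with an estimated correlation).

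The fatty acid oxidation and cholesterol synthesis lists were the other 2 called lower. The oxidation list shares Cpt1b (log2 fold change -0.73) and Ppargc1a (-0.60) with the brown adipocyte list, so their calls are not fully separate results. It was not tested without these shared genes. Of 21 fatty acid oxidation genes, 1 was lower, both over all genes and when adjusted over the list alone. It was Acadvl, the very long chain acyl-CoA dehydrogenase (127.0 ± 9.82 to 78.9 ± 6.25 CPM), and the list's median was -0.21 (camera adjusted p = 0.00825, and adjusted p = 0.869 with an estimated correlation). Of 19 cholesterol synthesis genes, 1 was lower, and adjusted over the list alone 4 were lower and 1 was higher. Insig1, which holds back the processing of sterol regulatory proteins, fell from 53.3 ± 7.45 to 29.4 ± 3.12 CPM, while the mevalonate pathway genes Mvk (log2 fold change -0.79) and Mvd (1.15) had adjusted p-values of 0.0736 and 0.0569 in edgeR's test. The median was -0.29 (camera adjusted p = 0.00825, and adjusted p = 0.869 with an estimated correlation). The call of the oxidation list was lost without control replicate 3 (median -0.13, camera adjusted p = 0.0812). That of the cholesterol list was lost without knockout replicate 2 (median -0.19, camera adjusted p = 0.115), and its median was -0.17 without control replicate 3 and -0.50 without knockout replicate 3.

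The 13 protein-coding genes of mitochondrial DNA were higher as a list, with a median log2 fold change of 0.72 (camera adjusted p = 1.24e-05, and adjusted p = 0.869 with an estimated correlation). By edgeR 0 of the 13 were called over all genes, 11 had an unadjusted p under 0.05, and 11 were higher when adjusted over the list alone. DESeq2 and limma each called 9 higher. The complex I subunits mt-Nd5 (5265 ± 1130 to 10380 ± 1830 CPM) and mt-Nd1 (5432 ± 1410 to 10200 ± 1040 CPM) came closest, with edgeR adjusted p-values of 0.0546 and 0.0652. Together the mitochondrial messenger RNAs took 8.13% ± 2.61 of counts in controls and 13.1% ± 1.55 in knockouts (SD, n = 3). A two-sided exact permutation test of that share gave p = 0.1, the smallest that 3 against 3 libraries allow. The lowest share, 5.52%, was in control replicate 2, the library with the high mitochondrial ribosomal RNA, and without it the list's median was 0.52 (camera adjusted p = 3.66e-05). The 35 nuclear oxidative phosphorylation genes had a median of 0.11, with 0 called by edgeR, 3 at an unadjusted p under 0.05, 1 called by DESeq2 and 2 by limma.

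Interferon response genes were higher as a list (27 members, median 0.36, camera adjusted p = 0.0222, and adjusted p = 0.869 with an estimated correlation), with 23 positive and 4 negative log2 fold changes. By edgeR 0 members were called over all genes or when adjusted over the list alone, 6 had an unadjusted p under 0.05 (among them Irf1, which was lower at -0.74), DESeq2 called 1 and limma 2. These shares were no higher than those of all 16139 tested genes, with 3665 at an unadjusted p under 0.05, 1501 called by DESeq2 and 1918 by limma. Irf9, a subunit of the interferon-stimulated transcription factor complex, had the smallest p (log2 fold change 0.72, edgeR adjusted p = 0.0639). The list lost its call without control replicate 1 (camera adjusted p = 0.205), control replicate 2 (0.0674), knockout replicate 1 (0.0892, median 0.22) or knockout replicate 2 (0.115). Endothelial and macrophage markers had positive medians of 0.36 and 0.28 and were not called as lists (camera adjusted p = 0.166 and 0.251).

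Contractile genes of smooth muscle were not shifted as a list (28 members, median -0.11, camera adjusted p = 0.33). Tagln, which encodes the actin-binding protein transgelin (SM22; ENSMUSG00000032085; chromosome 9, 45929619 to 45936058), was the 1 member that edgeR called over all genes, and fell from 5553 ± 1140 to 2526 ± 297 CPM, or 45.5% of control (log2 fold change -1.14 ± 0.19, edgeR adjusted p = 0.0331). An antisense gene overlaps Tagln, and without a stated strand setting their reads cannot be told apart. The log2 fold changes of Acta2 (-0.04 ± 0.17), Myh11 (-0.32 ± 0.16), Cnn1 (-0.02 ± 0.17) and Myocd (0.24 ± 0.43) did not pass the test. Adjusted over the list alone, 4 members were lower and 2 were higher. Of the 28 members 10 had an unadjusted p under 0.05, and DESeq2 called 3 higher and 5 lower and limma 3 higher and 4 lower. The lack of a shift of the list therefore does not mean that its other members were unchanged, as they moved both ways. The Tagln call was kept without control replicate 2 and lost without any other single library, with edgeR adjusted p-values of 0.114 and 0.0588 without control replicates 1 and 3 and 0.186, 0.156 and 0.079 without knockout replicates 1 to 3. Its log2 fold change stayed between -1.29 and -1.03 in the 6 fits with 1 library left out.

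Genes of modulated smooth muscle (22 members) had 2 rises, S100a4 (46.6 ± 8.11 to 97.9 ± 14.6 CPM) and Tnfrsf11b, the decoy receptor osteoprotegerin (20.3 ± 2.99 to 33.7 ± 2.91 CPM). Adjusted over the list alone, 5 were higher and 1 was lower, and the list was not called (camera adjusted p = 0.093). Of 17 osteochondrogenic genes, 2 rose and 1 fell. The cartilage proteoglycan gene Acan (21.7 ± 4.68 to 69.7 ± 10.9 CPM) rose along with Tnfrsf11b, and Sost, which encodes the Wnt inhibitor sclerostin, fell from 1382 ± 359 to 446.6 ± 133 CPM. Adjusted over the list alone, 4 were higher and 1 was lower, and the list was not called (camera adjusted p = 0.291). Runx2 (0.22 ± 0.32) and Spp1 (-0.61 ± 0.79) did not pass the test. Of 32 collagen and elastic fibre genes, the microfibril gene Mfap4 was the 1 that fell (272.8 ± 58.7 to 120.7 ± 11 CPM), and adjusted over the list alone 3 were lower.

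Glycolysis genes (22 members) had 2 rises over all genes and 2 when adjusted over the list alone, the lactate transporter Slc16a3 (19.9 ± 2.18 to 42.1 ± 5.24 CPM) and Pgam1 (96.3 ± 4.40 to 144.8 ± 11.7 CPM). Calcium handling and vasoreactivity genes (29 members) had 2 rises, the serotonin receptor Htr1b (log2 fold change 1.08 ± 0.20) and Rgs4 (0.73 ± 0.14), and adjusted over the list alone 3 were higher and 2 were lower. In the p53 list (19 members) Fas rose and Gadd45a and Btg2 fell. The heat shock list had 1 rise, Dnaja1, the circadian list 1 fall, Nr1d1, the integrated stress response list 1 fall, Ppp1r15a, the matrix protease list 1 rise, Timp4, and the calcification inhibitor list 1 rise, Tnfrsf11b. Adjusted over the list alone, 2 members were higher and 2 lower in the p53 list, 1 higher and 1 lower in the integrated stress response and calcification inhibitor lists, and the heat shock, circadian and matrix protease lists had the same 1 member. None of these lists was called by camera. In the unfolded protein response list (20 members) edgeR called 0, while 4 had an unadjusted p under 0.05, 3 were lower when adjusted over the list alone, and DESeq2 and limma each called 3 lower. Hspa5, the chaperone BiP, had 341.8 ± 69.6 CPM in controls and 192.3 ± 23.3 CPM in knockouts (edgeR adjusted p = 0.0532).

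**Figure D2:**
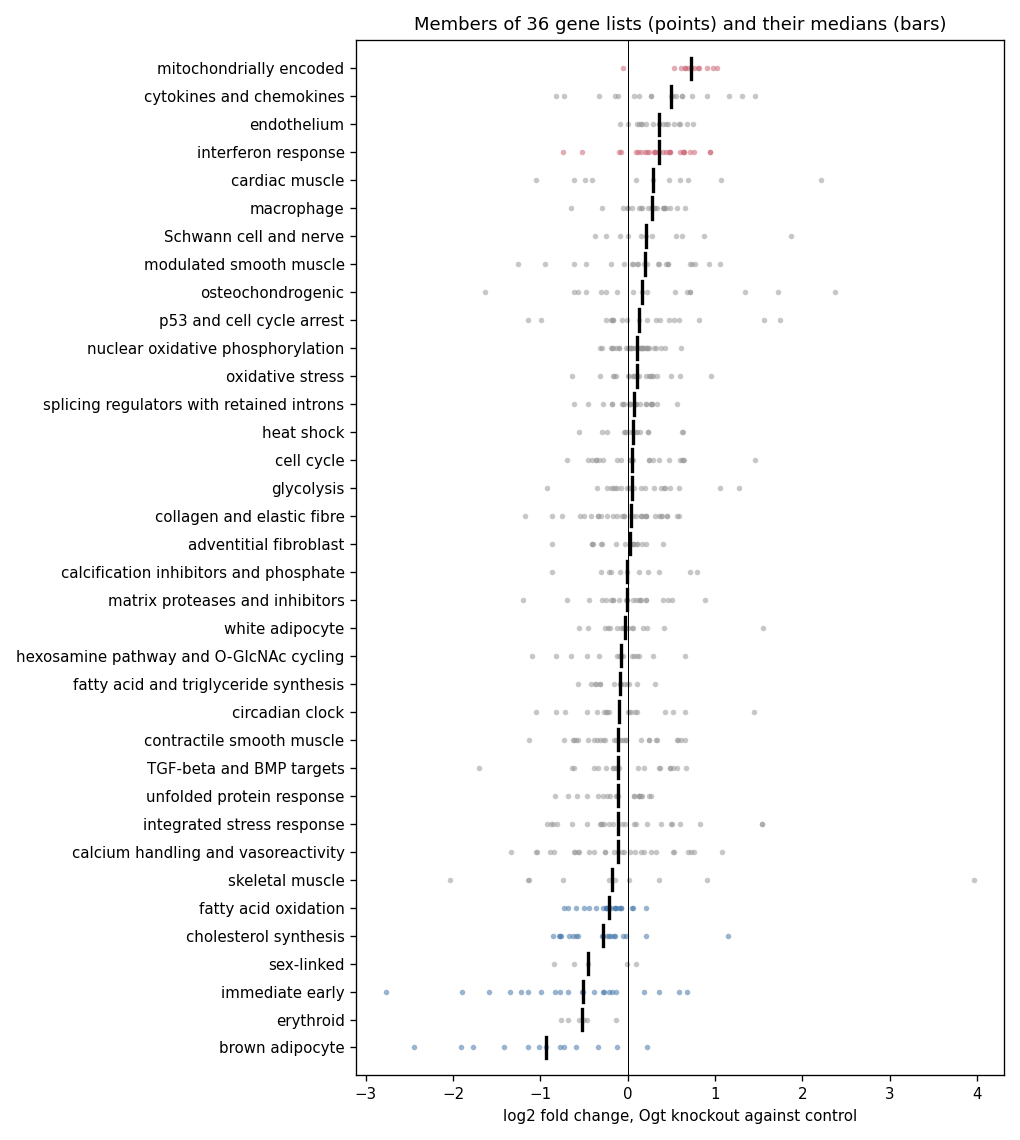
Log2 fold changes of the tested members of each of 36 gene lists (points), with the list median (black bar); the horizontal axis is knockout against control. Coloured points mark lists called by camera with the preset correlation, the 2 higher ones in red and the 4 lower ones in blue, and the brown adipocyte list lies lowest with a median of -0.94.

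Markers of other cell types gave few calls. Cardiac muscle genes (11 members) had 2 rises, Actc1 (3.37 ± 2.02 to 17.7 ± 4.06 CPM) and Ankrd1 (11.6 ± 1.49 to 24.8 ± 4.06 CPM), skeletal muscle genes (10 members) had Ckm higher and Casq1 lower, and the epithelial keratin Krt18 was the 1 mesothelium marker called. Adjusted over each list alone, the same number of members passed in these 3 lists. By edgeR 0 tested members of the endothelium, macrophage, adventitial fibroblast, Schwann cell, erythroid, lymphocyte and neutrophil lists were called, and DESeq2 and limma also called 0, with 3 fibroblast and 1 Schwann cell marker at an unadjusted p under 0.05. Only 3 of 20 lymphocyte, 2 of 13 neutrophil and 2 of 10 mesothelium markers were tested. The lymphocyte, neutrophil and mesothelium lists were thus too small for camera, and their calls say little about those cells. List medians were 0.02 for fibroblasts, 0.20 for Schwann cells and -0.53 for erythroid genes. Xist had 1.25 ± 0.274 and 0.771 ± 0.30 CPM and the Y-linked Ddx3y 103.5 ± 21.6 and 103.1 ± 16.2 CPM in controls and knockouts, so all 6 libraries had male-type expression of both genes. The lists for cell cycle, oxidative stress, cytokines, fatty acid synthesis, splicing regulators and TGF-beta and BMP targets had no member called by edgeR and were not called as lists (medians 0.05, 0.10, 0.49, -0.09, 0.07 and -0.11), and adjusted over the list alone 1 TGF-beta and BMP target was lower. The sex-linked list was not called either (median -0.46, camera adjusted p = 0.42). Across the 17 tested lists with no member called, 57 of 316 entries had an unadjusted p under 0.05, DESeq2 called 23 and limma 28. Of all 16139 tested genes 3665 had an unadjusted p under 0.05, DESeq2 called 1501 and limma 1918, so the shares of the pooled lists were no higher. Single lists differed, with 11 of 13 mitochondrially encoded and 0 of 15 fatty acid synthesis genes at an unadjusted p under 0.05. Of the 20 TGF-beta and BMP targets 9 were under it, while DESeq2 called 1 higher and 2 lower and limma 3 higher and 1 lower. In 7 lists, none of them called, the median, the mean and the direction of the test differed in sign. These were the adventitial fibroblast, integrated stress response, TGF-beta and BMP, white adipocyte, matrix protease, calcification inhibitor and collagen and elastic fibre lists.

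Camkk1 lies beside Atp2a3 and P2rx1 on chromosome 11, and both of these also rose. They lie outside the naming rule and were chosen after their values were seen. Atp2a3, a calcium pump of the endoplasmic reticulum (72961169 to 72993044), went from 216.3 ± 19.1 to 1079 ± 153 CPM, and P2rx1, an ATP-gated ion channel (72999103 to 73015200), from 87.4 ± 41.5 to 541.1 ± 61.8 CPM, with edgeR adjusted p-values of 0.0023 and 0.0178. A predicted gene between P2rx1 and Camkk1 had a log2 fold change of 0.34 ± 0.59. Of the 25 other tested genes within 1 Mb, edgeR called 0, 5 had an unadjusted p under 0.05, DESeq2 called 2 and limma 3. The shares were similar over all 16139 tested genes, where edgeR called 557, 3665 had an unadjusted p under 0.05, DESeq2 called 1501 and limma 1918. The Atp2a3 call was kept without each library in turn. P2rx1 lost its call without control replicate 1 (edgeR adjusted p = 0.0806) and without knockout replicates 1, 2 and 3 (0.0873, 0.0837 and 0.0522), and Camkk1 lost its call without control replicate 1 (0.0764). With 1 library left out, log2 fold changes ran from 2.445 to 3.097 for P2rx1 and from 3.059 to 3.544 for Camkk1.

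**Figure D3:**
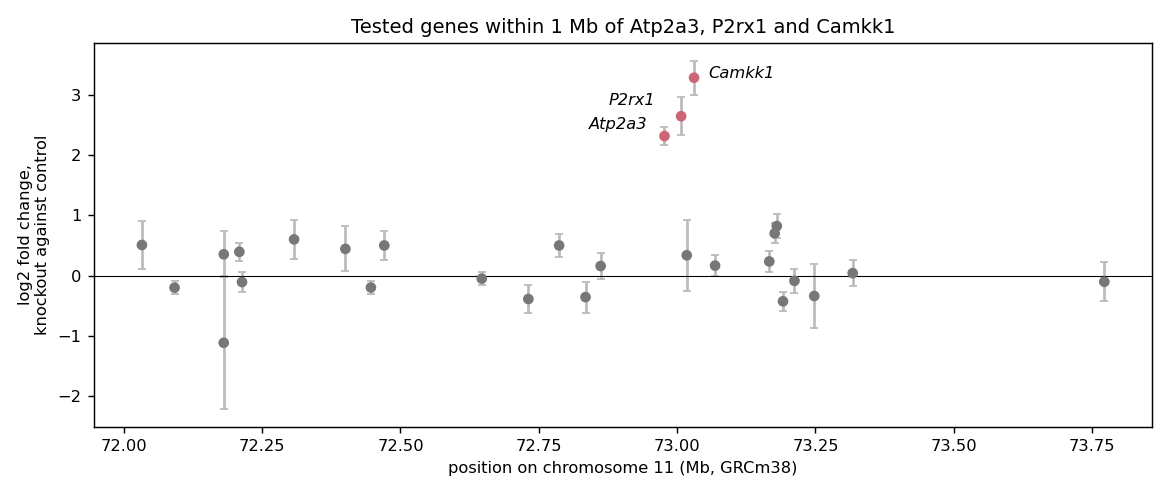
Log2 fold change, knockout against control, of each tested gene within 1 Mb of Atp2a3, P2rx1 and Camkk1, plotted at its midpoint on chromosome 11 in GRCm38 coordinates, with bars of 1 SE. The 3 labelled genes, in red, passed the edgeR threshold with log2 fold changes of 2.32, 2.65 and 3.29, and the 25 others, in grey, did not.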

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

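Tests on protein-coding genes only and on the lists without Ogt or Ucp1 were chosen after seeing the data, and the other alternatives were planned. Against 306 higher and 251 lower genes, scaling by library size gave 94 and 99, DESeq2 759 and 742 (1607 adjusted p-values not given), limma-voom with sample weights 946 and 972, a minimum absolute log2 fold change of 1 gave 156 and 115, and removal of the gene length trend 506 and 417. Leaving out 1 library gave 4 to 491 higher and 3 to 420 lower genes, with fewer libraries in each such fit. The cause of the other shifts was not tested. DESeq2 size factors, no filter, the 1 CPM filter, robust estimation off, the GC trend and protein-coding genes only (375 and 349) stayed within 1.5 times the counts. Of the 557 genes, 543 were shared with the DESeq2 calls, 557 with limma and 521 with the calls without control replicate 2. All 557 had the same direction in each of these, which could hardly be otherwise for genes whose groups do not overlap. The Ogt log2 fold change ranged from -1.23 to -1.02 with 1 library left out, and the other settings except the replicate block kept its call.

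The replicate numbers gave no clear pairing of the libraries, as deviations of same-numbered libraries correlated at 0.05, 0.09 and -0.06. Control replicates 1 and 2 correlated best with their own number and control replicate 3 did not. With 3 libraries per group, these values cannot exclude a pairing. With the replicate block there were 18 higher and 10 lower genes and Ogt was at -1.11 (edgeR adjusted p = 0.0572), with 2 lists higher and 5 lower.

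Lists called higher, 2 in all, numbered 10 with no filter, 0 with an estimated correlation, 0 with fry and 1 to 6 with 1 library left out. Lists called lower, 4 in all, numbered 0 with an estimated correlation and 2 with fry (brown adipocyte and immediate early genes, adjusted p = 0.0477 each). With the estimated correlation in camera 2 of the 36 lists had an unadjusted p under 0.05, which is near the number that chance gives. The smallest adjusted p of camera in that setting was 0.786. Without Ucp1 the brown adipocyte median was -0.86 (camera adjusted p = 0.000353), and without Ogt the hexosamine list was still not called. No named gene or list called in either of the fits compared changed direction, while some that were called in neither did, among them 3 lists with fry and 6 named genes without knockout replicate 2. Alternatives for tables without counts (pseudocounts, filters on low values) did not apply.

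The 6 libraries split into 3 and 3 in 10 ways, so the share of splits with as many genes can never be under 0.1. The real split, 1 of the 10, gave 306 and 251 genes, and the highest count of any other split was 2 in either direction. Each other split puts control and knockout libraries in both groups. A real group difference then adds to the spread within groups, so these low counts do not show what chance alone gives. At these depths, this spread and 3 libraries per group, 29% of simulated 2-fold changes were called, and the part that depth has in this was not tested.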

Other observations

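The tests on the chromosome 11, Tagln and brown adipocyte patterns below were chosen only after those results had been seen. Outside the naming rule, and chosen after their values were seen, Haus8 and Phkg1 were among the 7 genes that passed the edgeR threshold in each of the 6 fits with 1 library left out, the others being Ckm, Ctxn1, Ucp1, Zfp62 and Atp2a3. Haus8, a subunit of the augmin complex of the mitotic spindle, rose from 46.6 ± 8.65 to 257.7 ± 25.5 CPM (SD, n = 3). Phkg1, a catalytic subunit of the phosphorylase kinase that starts glycogen breakdown in muscle, fell from 68.5 ± 1.52 to 23.9 ± 1.84 CPM. Cell cycle genes gave no call beside Haus8, with 0 of 23 called by edgeR, 2 at an unadjusted p under 0.05, 0 called by DESeq2 and 1 by limma.

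Atp2a3, P2rx1 and Camkk1, neighbours on chromosome 11 (72961169 to 73042073), rose by log2 fold changes of 2.32, 2.65 and 3.29. Of the tested genes, 33 were called with a rise of at least 2 log2 units. In a share of 4e-04 of 10000 random gene orders, 3 or more of them lay within 100 kb. That share decides nothing, since its limits were taken from the cluster. Over 5 window sizes and 3 fold minimums (15 settings), set against the fullest window anywhere in the genome, the share was 0.0016. For windows of 100 to 1000 kb it was 5e-04 to 0.016 at a minimum of 2 log2 units. At a minimum of 1 it was 0.041 for 100 kb and 0.12 to 0.77 for 200 to 1000 kb, and at 0 it was 0.25 or more. The low share thus rests on the fold minimum taken from the cluster, and chance clustering is not excluded. Control replicate 2 is not the source, since without it all 3 neighbours were called and the lowest log2 fold change was 2.36. A local difference in the DNA of the knockout mice, such as a Cre transgene or linked strain DNA, cannot be told apart from loss of Ogt, as the labels do not say whether controls carried Cre. Of the 25 other tested genes within 1 Mb, 0% were called by edgeR (2 genes by DESeq2, 3 by limma, 5 at an unadjusted p under 0.05). The shares over all 16139 tested genes were similar (557 by edgeR, 1501 by DESeq2, 1918 by limma, 3665 at an unadjusted p under 0.05). These counts therefore neither show nor exclude a wider change of the region. Loss of Ogt may act on Atp2a3, P2rx1 and Camkk1 through shared local regulation, which was not tested.

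Tagln fell with a log2 fold change of -1.14 (95% interval -1.52 to -0.76). That interval assumes a normal distribution and is too narrow for 3 libraries per group. A smaller share of smooth muscle RNA, as the whole cause, is argued against by the other 27 contractile genes, whose median was -0.087. The 95% bootstrap interval of that median (-0.32 to 0.15) came from resampling genes and does not measure the spread between libraries. Loss of 1 Tagln copy to a Cre allele cannot be told apart from an effect of Ogt loss: the Tagln interval includes -1, sample titles carry the name SM22 (Tagln), and the labels do not say whether controls carried Cre. At the same locus, and chosen after their values were seen, Pcsk7 (chromosome 9, 45906497 to 45929726), which ends inside the Tagln gene, rose from 27.8 ± 2.20 to 59.0 ± 5.35 CPM (edgeR adjusted p = 0.0157, but 0.0806 without control replicate 1 and 0.0838, 0.0874 and 0.051 without knockout replicates 1 to 3), the antisense gene Gm48529 inside Tagln had a log2 fold change of -1.31 (0.029), its reads not separable from those of Tagln, and Sidt2 on the other side had 0.37 (0.12). A change in the DNA of this locus and a response to Ogt loss both remain candidate explanations, and genotyping reads across Tagln would be needed to separate them.

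Brown adipocyte genes were lower as a list, with 4 of 13 members called and a median log2 fold change of -0.94 (95% bootstrap interval -1.41 to -0.60), a call that camera lost with an estimated correlation (adjusted p = 0.786). Less fat carried with the aorta, as the whole cause, is argued against by the 18 white adipocyte genes, whose median was -0.035 (-0.14 to 0.05). Both bootstrap intervals came from resampling genes and do not measure the spread between libraries. Of the 4 white adipocyte genes the naming rule took, none was called by edgeR, and their log2 fold changes went both ways, at 1.55 for Lep, 0.42 for Slc2a4, -0.56 for Pck1 and -0.46 for Plin1. Control replicate 2 does not account for the list's call with the preset correlation, since without it the list was called lower with a median of -0.83. A lower thermogenic state of the same fat, or a different mix of fat around the dissected vessel, may account for the pattern, and neither was tested.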
